A study of Mus musculus with 10 samples.

How the data were processed

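Liver RNA of 10 male mice that carry a miR-221 transgene (the strain TG221) was measured on Agilent 1-colour mouse expression arrays, 1 array per mouse. Per the labels, 6 mice received metformin with CCl4 and 4 received CCl4. The groups and the mouse numbers were taken from the sample titles. Total RNA with an integrity number above 8 was used, and 100 ng per sample was amplified and labelled with Cy3, per the labels' protocols.

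The deposited scanner files hold spot intensities on a linear scale, made with Agilent Feature Extraction version 10.7.3.1, per the file headers. The processed intensity used here had already been background-subtracted and detrended over the slide surface by that software, per the file headers, and was not normalized between arrays. The same deposited files give the median spot intensity, the median local background and flags for spots well above background, saturated or irregular. They have no mean spot intensity column, so the alternative background correction, planned on mean intensities, was run on the median ones. The authors also deposited a table of log2 values of 4595 probes in the 10 mice, quantile-normalized and limited to probes with FDR below 0.01 and a fold change above 1.5, per the file's first line. Neither the file nor the labels name the test behind that filter. The table had been taken beforehand for one of fold changes; it holds values per mouse, so differences of group means were computed from it. Its columns followed the log2 scanner intensities of their own arrays with a Pearson r of 0.9997 to 1.00 across probes, which fixes its direction and log2 scale. Its column medians were 7.87, 7.88, 7.84, 7.78, 7.81 and 7.81 for metformin mice 1 to 6 and 7.76, 7.79, 7.83 and 7.84 for CCl4 mice 1 to 4. Any centring beyond quantile normalization stays unknown.

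Each array held 59305 non-control spots for 55681 probes. Between 51.2% and 54.9% of the probes were well above background per array, no spot was saturated, and 135 to 179 spots per array were flagged as irregular and left out. Repeated spots of a probe on 1 array had a median SD of 0.058 to 0.071 on the log2 scale. The number of arrays, 6 and 4, limits the precision. The log2 of the processed intensity was taken, and the array's 75th percentile over non-control spots was subtracted. Spots of a probe were averaged. Probes well above background on at least 75% of the arrays of either group were kept, 29576 in all. Probes were named by matching their accessions, without versions, to the RefSeq gene table of assembly GRCm38.p6, used for names only because the arrays' grid file names build mm9. A symbol was found for 28664 probes (21613 genes), and 27017 probes stayed unnamed. A gene was represented by its probe with the highest mean signal over all 10 arrays, chosen without regard to group. The tests covered 22184 features, of which 14531 were named genes. Of the 6883 called genes, 1855 had more than 1 kept probe and 206 of these had another probe called in the opposite direction.

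Groups were compared with limma (version 3.58.1, in R 4.3.3; lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested features and adjusted p below 0.05 as the threshold. All adjusted p-values of genes come from limma. A fold change is metformin plus CCl4 over CCl4. A gene not well above background on any array of a group has only a bound there, given as at least N-fold: the brighter group's mean against the mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. For 19 features with a missing value, the group mean was filled in for the gene list tests. On data simulated from the gene means and residual SDs of this comparison (22184 features), limma recovered 66% of 100 genes changed 2-fold and 30% of 100 genes changed by 0.5 on the log2 scale, with 8 false calls (7.69% of calls). The list test called the 1 list that had been moved and 0 others. The simulated genes were independent and few were changed, whereas the estimated correlation was 0.31 within the matrix list and 0.52 within the ribosomal list. The simulation therefore cannot show how the list test behaves on correlated genes or how limma does with many changed genes. Figures were drawn with matplotlib 3.10.9.

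Before the data were examined, 38 gene lists (1062 entries, 948 of them tested) were fixed, and 37 had the minimum of 5 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01. The shift of a list is the median log2 fold change of its members minus the median of all tested features, which was 0.10. A list's genes below background in a group, present in 2 lists, moved no list median (largest move 0) when set at their bound. Camera with an estimated correlation and fry were alternatives. An exact permutation test of list scores was added after seeing the data: the score is the mean of a list's members on an array minus the mean of all tested features, compared over all 210 splits of the arrays into 6 and 4 (two-sided, smallest possible p 0.00476), with Benjamini-Hochberg adjustment over the 37 lists.

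The genes named in the text follow a rule fixed beforehand: the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, leaving out clone and predicted names; up to 4 members with the smallest p of each called list and of 9 lists on metformin or liver injury, the miR-221 targets among them; and Col1a1, Acta2, Afp, G6pc, Cyp2e1, Mki67 and Cdkn1b whatever their values. Other names were chosen after their values were seen, which is said where they appear. The alternatives were normexp (offset 50) on median intensities, quantile and median normalization, no filter and a filter on all 10 arrays, other probe summaries, irregular spots kept, other variance models, a 1.5-fold minimum, slide row 1 alone or slide row as a covariate, the mouse number as a block, and leaving out each array. Scaling to 8 E1A spike-in transcripts was added after seeing the data. The metformin arrays lay on slide 1 and the CCl4 arrays on slide 2, scanned on different days, so slide, scan day and group cannot be told apart. All CCl4 arrays and 2 metformin arrays lay on slide row 1, and row 2 held only the other 4 metformin arrays. With slide row as a covariate the group difference therefore rests on the 2 metformin arrays of row 1, as with row 1 alone. The arrays of row 2 then add only to the estimate of spread.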

Results

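Gene expression was measured in the livers of 10 male TG221 mice on a B6D2F2 background. TG221 mice overexpress miR-221, a microRNA that is raised in many liver cancers. From 4 to 6 weeks of age all mice were given 20% (v/v) carbon tetrachloride (CCl4), a liver toxin that causes fibrosis, by gavage 3 times a week for 14 weeks. In 6 of them metformin, a biguanide used against type 2 diabetes, was added at 300 mg/kg daily from 3 weeks after the first CCl4 dose, and 4 mice had CCl4 alone. Livers were taken at 24 weeks. The labels give both liver and hepatocellular carcinoma for these samples, and the series holds no mice without CCl4. The 75th percentile of the processed spot intensity ran from 237 to 363 over the arrays.

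The design asks which genes and gene sets differ between livers of CCl4-treated mice with and without metformin. Of 14531 named genes tested, 4024 were higher and 2859 lower with metformin at an adjusted p below 0.05 in limma, which is 47.4% of them. The change was at least 2-fold for 804 of the higher and 781 of the lower genes. In 5223 genes (35.9%) the 6 metformin mice did not overlap the 4 CCl4 mice, against 0.952% by chance. The first principal component held 52.0% of the variance and separated the groups. Arrays correlated at 0.984 to 0.993 within groups and at 0.963 to 0.976 between groups, across genes, which are not independent replicates. The split of the calls, 58.5% higher and 41.5% lower, depended on the scaling: it was 50.4% higher after median scaling and 7.52% higher after scaling to spike-in transcripts, which put the median change of all features at -0.45 in place of 0.10. Each group was hybridised on a slide of its own, so slide and scan day cannot be told apart from metformin. Of 37 gene lists tested, camera called 18 at its preset correlation, 3 higher and 15 lower. After scaling to spike-ins it called 4, and of the 18 only the matrix, proliferation and NRF2 lists were left. That scaling subtracts 1 value per array, so the median of a list relative to all features stayed the same, at -1.02 for neutrophil markers and 0.21 for ribosomal proteins. With an estimated correlation camera called 0 (0 at an unadjusted p below 0.05), and 19 of 100 splits of the arrays, the real one included, gave at least 18 lists at the preset correlation. Fry, which tests a list against no change and not against other genes, called 13 of the 18 lists, and an exact permutation test of list scores called 11.

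Among called genes whose groups did not overlap, the largest fitted fall was that of Cdkn1a, the cyclin-dependent kinase inhibitor p21, which was 22.6-fold lower with metformin (log2 fold change -4.50 ± 0.52 SE, adjusted p = 1.27e-04, n = 6 and 4). Hamp2, a paralog of the iron hormone hepcidin, was 16.6-fold lower, but its level differed between CCl4 mice, at 3.55, 8.50, 8.44 and 3.67 on the log2 scale for mice 1 to 4, its log2 fold change ran from -4.88 to -3.23 when 1 CCl4 mouse was left out, and cross-hybridisation with Hamp was not excluded. The clock transcription factor Arntl was 10.1-fold lower. Npas2, another clock transcription factor, was at least 3.74-fold lower, since no metformin array showed it well above background. Wfdc6b was at least 2.95-fold, the epithelial transcription factor Elf3 at least 3.03-fold and Ccnjl at least 3.61-fold lower by the same reckoning. Denn2b, Ccdc120, Tmem171, Olig1 and Vmn1r197 had log2 fold changes of -3.10, -3.08, -3.02, -2.91 and -2.89. Tmem171 was well above background on 3 and Vmn1r197 on 1 of the 6 metformin arrays. The largest fitted rise among such genes was that of Ihh, which encodes the signalling protein Indian hedgehog, at 3.99 ± 0.74 on the log2 scale (adjusted p = 0.00166), with 2 of 4 CCl4 arrays well above background; it was 3.28 without CCl4 mouse 3 and 4.73 without CCl4 mouse 4. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 6.91-fold (adjusted p = 5.00e-05). The clock gene Per3 was at least 4.37-fold higher, and Zmynd10, Senp8, Ap4e1 and Nkapl were at least 2.94-, 2.34-, 2.67- and 2.28-fold higher, none of these 5 being well above background on any CCl4 array. Plcxd2, Kctd21, Prr18, Clec2d and Pde6c rose by 3.16, 3.03, 2.84, 2.82 and 2.81 on the log2 scale, with Kctd21 and Pde6c well above background on 3 and Prr18 on 1 of the 4 CCl4 arrays; Plcxd2 was at 3.82 without CCl4 mouse 4. Of these 24 genes, 9 have only a bound, so their rank by fitted value is not established. With normexp 17 of the 24, these 9 among them, had changes smaller by over 1.5 times (Ihh 1.62, Kctd21 1.62, Pde6c 1.13, Prr18 0.62, Olig1 -1.99, Ccdc120 -1.73, Tmem171 -1.09 and Vmn1r197 -0.68) and stayed called. With slide row 1 alone (2 metformin mice), Ihh and Hamp2 lost their calls, at 3.13 and -4.39 and adjusted p = 0.0821 and 0.0975 in limma, while Cdkn1a was at -5.25 and Tmem171 at -3.64 (ranges over alternatives 3.76e-04 to 0.0821 and 0.00123 to 0.0975).

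**Figure D1:**
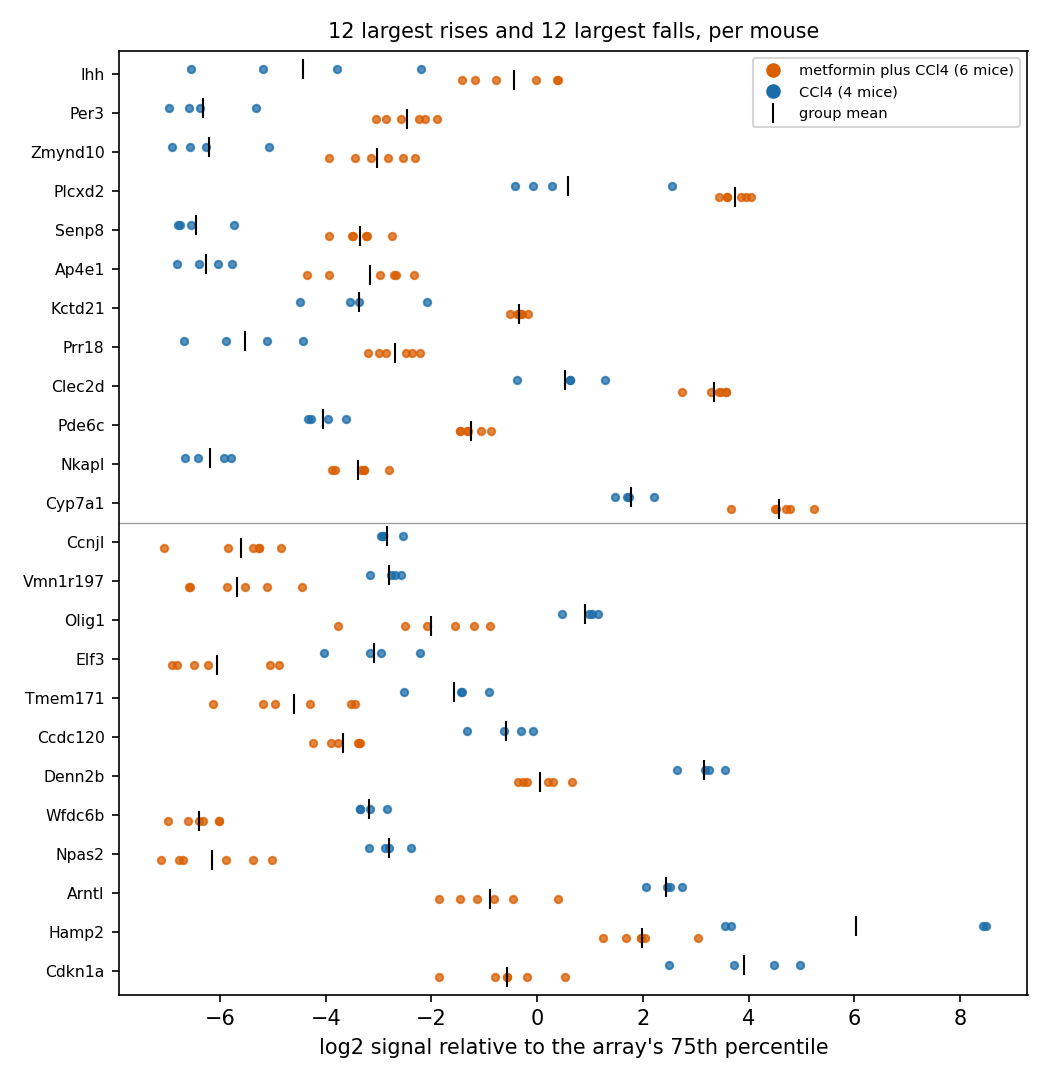
Log2 signal relative to the array's 75th percentile (horizontal axis) of the 12 genes with the largest fitted rise (top) and the 12 with the largest fitted fall (bottom) among called genes whose groups do not overlap; each point is 1 mouse and bars are group means. Values of Per3, Zmynd10, Senp8, Ap4e1 and Nkapl in CCl4 mice and of Ccnjl, Elf3, Wfdc6b and Npas2 in metformin mice are not well above background, and Hamp2 is at 8.50 and 8.44 in a pair of CCl4 mice and at 3.55 and 3.67 in the other pair.

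Genes of the fibrotic extracellular matrix were lower with metformin. Of 40 measured members, 28 fell, 1 rose and 11 did not pass the test; adjusted over the list alone, 31 fell and 1 rose. The list's shift relative to all features was -0.98. The basement membrane collagens Col4a1 and Col4a2 had log2 fold changes of -2.17 ± 0.17 and -1.36 ± 0.12, the proteoglycan Bgn -1.68 ± 0.13 and the collagen crosslinking enzyme Loxl1 -2.59 ± 0.32 (SE; -1.95 by a second kept probe), each lower in all 6 metformin mice than in all 4 CCl4 mice. Fn1, fibronectin, was the member that rose (0.89), named here after its value was seen. Col1a1, the main fibrillar collagen chain, differed by -1.004 ± 0.42 and did not pass (adjusted p = 0.0733 in limma). Among other settings it passed without metformin mouse 3 or 4 or CCl4 mouse 1 (adjusted p = 0.0456, 0.0369 and 0.0441), with normexp (adjusted p = 0.0331) and after scaling to spike-ins (adjusted p = 0.0115), within a range of 0.0115 to 0.201. Camera called the matrix list (adjusted p = 3.42e-10), with adjusted p = 0.574 with an estimated correlation and adjusted p = 0.0176 in the exact permutation test of list scores.

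Markers of activated stellate cells and myofibroblasts, the main matrix-producing cells of the liver, also fell. Of 24 members, 10 were lower, 1 higher and 13 not called, with the same counts adjusted over the list alone (10 lower and 1 higher) and a shift of -0.42. Reln, Des, Ngfr and Itga8 had log2 fold changes of -1.59, -1.28, -1.54 and -1.55. Acta2, the smooth muscle actin of myofibroblasts, fell by 0.71 ± 0.22 (adjusted p = 0.0246 in limma), and this call was lost without CCl4 mouse 2 or 4 (adjusted p = 0.0751 and 0.0671, range over alternatives 0.00156 to 0.0979). For the list, camera gave an adjusted p = 0.00549, adjusted p = 0.574 with an estimated correlation, and the exact permutation test adjusted p = 0.0294.

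Proliferation genes were lower: of 52 members, 27 fell, 6 rose and 19 were not called (28 and 6 adjusted over the list alone), and the shift was -0.52. The replication helicase subunit Mcm5 had a log2 fold change of -1.23, the chromatin protein Hmgb2 -1.04, cyclin A2 (Ccna2) -1.57 and the cytokinesis regulator Racgap1 -0.90, where a second kept probe gave -1.76. Slide row 1 alone and leaving out metformin mouse 1 gave -1.98 and -1.73 for Racgap1, but the probe is picked anew in each fit. The first probe, at -2.74 to -2.29 in metformin and -1.74 to -1.39 in CCl4 mice, cannot give these values, so they reflect the second probe. Mki67, the proliferation marker Ki-67, fell by 0.96 ± 0.18 (adjusted p = 0.00194 in limma), a call lost with slide row 1 alone (-0.75, adjusted p = 0.0583, range 8.53e-04 to 0.0583). Camera called the proliferation list (adjusted p = 5.82e-05), with adjusted p = 0.574 with an estimated correlation and adjusted p = 0.0176 in the exact permutation test. Genes of hepatocellular carcinoma and the fetal liver had 10 lower, 2 higher and 18 uncalled members of 30 (9 and 2 adjusted over the list alone) and a shift of -0.43. S100a11, Anxa5 and Sox4 had log2 fold changes of -1.27, -0.76 and -0.98, while Ctnnb1 (beta-catenin) was at 0.50 and came to -0.058 after scaling to spike-ins. Afp, alpha-fetoprotein, differed by -0.30 ± 0.28 and did not pass (adjusted p = 0.398 in limma), but passed after scaling to spike-ins (adjusted p = 0.0146, range 0.0146 to 0.882). Markers of bile duct cells and progenitors had 7 lower, 1 higher and 9 uncalled of 17 (9 and 1 adjusted over the list alone) and a shift of -0.70, with the keratins Krt7 and Krt19 at -1.14 and -1.17, Cd24a at -0.93 and the chloride channel Cftr higher at 0.80, a call lost after scaling to spike-ins (0.24, adjusted p = 0.380). The carcinoma and bile duct lists share 5 members, 3 of which fell (Cd24a, Epcam and Prom1, the last 2 named after their values were seen), so they are not independent. Camera gave adjusted p = 0.0109 for the carcinoma list and 0.0108 for the bile duct list, each with adjusted p = 0.574 with an estimated correlation; the exact permutation test gave adjusted p = 0.0176 and 0.0378. The bile duct call was lost with slide row as a covariate (shift -0.75, adjusted p = 0.0513) and without CCl4 mouse 4 (adjusted p = 0.0503), within a range of 6.25e-04 to 0.194 over alternatives at the preset correlation.

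Ribosomal protein genes were higher relative to other genes: 38 of 54 rose, 0 fell and 16 were not called (44 rose adjusted over the list alone), with a shift of 0.21. Rps21, Rps23, Rps20 and Rpl26 had log2 fold changes of 0.69, 0.58, 0.66 and 0.51; scaled to spike-ins these were 0.14, 0.020, 0.11 and -0.047, so Rpl26 changed sign; its other kept probes were at 0.95 and 0.53, and at 0.39 and -0.024 after that scaling, so the sign depends on the probe. Subunits of mitochondrial complex I, which metformin is known to inhibit, had 19 of 37 higher, 0 lower and 18 uncalled (19 higher adjusted over the list alone) and a shift of 0.15. Ndufa8, Ndufb4, Ndufb2 and Ndufa6 were at 0.61, 0.65, 0.61 and 0.54, and scaled to spike-ins at 0.055, 0.093, 0.051 and -0.016. Complexes II to V had 16 higher, 2 lower and 20 uncalled of 38 (17 and 2 adjusted over the list alone) and a shift of 0.13. Camera's direction for them reversed after scaling to spike-ins (adjusted p = 0.991). Uqcrfs1, Cox7c and Sdhd were at 0.54, 0.53 and 0.41, and at -0.013, -0.022 and -0.14 after scaling to spike-ins (0.046 and 0.33 by the other kept probes of Cox7c), and Uqcrc1 was lower at -0.48. Camera called the 3 lists (adjusted p = 9.42e-07, 0.00284 and 0.0111), with adjusted p = 0.574, 0.574 and 0.638 with an estimated correlation and adjusted p = 0.0176, 0.0176 and 0.0294 in the exact permutation test. After quantile normalization both mitochondrial calls were lost (adjusted p = 0.0723 for complex I and 0.288 for complexes II to V, within ranges of 6.05e-05 to 0.614 and 8.83e-04 to 0.991 at the preset correlation). The call of complexes II to V was also lost with slide row 1 alone (shift 0.067, adjusted p = 0.0709) and with slide row as a covariate (0.076, adjusted p = 0.0530). Both of these fits rest on the same 2 metformin arrays.

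Markers of several blood-derived and vascular cells were lower in these bulk livers. Of 29 macrophage and monocyte markers 10 fell, 0 rose and 19 were not called (8 fell adjusted over the list alone), with a shift of -0.48. The complement gene C1qb was at -1.22, Cd68 at -0.70, Cd14 at -0.90 and Lgals3 at -0.62. Of 14 neutrophil markers 7 fell, 1 rose and 6 were not called (7 and 1 adjusted over the list alone), with a shift of -1.02. Retnlg and Ngp were at -1.89 and -1.82, and S100a8 at -1.41, a call lost without CCl4 mouse 1 (adjusted p = 0.0633 in limma, range 7.65e-04 to 0.0698). Csf3r, the receptor of a neutrophil growth factor, was higher at 0.45, and at -0.11 after scaling to spike-ins. Its mean log2 signal was 7.13 in metformin and 6.69 in CCl4 mice, against 1.28 and 2.69 for S100a8. Whether its probe also measures another transcript was not tested. Of 11 class II antigen presentation genes 5 fell, 1 rose and 5 were not called (5 and 1 adjusted over the list alone), with a shift of -0.40. Cd74, H2-DMa and H2-Aa were at -1.07, -0.84 and -1.10, and the costimulatory gene Cd80 at 0.56, a call lost after scaling to spike-ins (8.5e-04, adjusted p = 0.997). Of 10 erythroid and blood markers 6 fell, 1 rose and 3 were not called (6 and 1 adjusted over the list alone), with a shift of -0.78. The platelet gene Itga2b, Hbb-b1, Alas2 and Hba-a1 were at -1.16, -1.02, -0.66 and -0.995, and the globin copies cannot be separated with certainty by their probes. Of 26 endothelial markers 7 fell, 1 rose and 18 were not called (7 and 1 adjusted over the list alone), with a shift of -0.32. Vwf, Pecam1 and Plvap were at -1.28, -0.88 and -0.85 and Erg at 1.38, while the sinusoidal markers Stab2 and Clec4g, named after their values were seen, differed by -0.26 and -0.058 without passing.

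Camera gave adjusted p = 0.00521 for macrophages, 0.0174 for neutrophils, 0.0276 for class II genes, 0.0108 for blood and 0.0111 for endothelium, against adjusted p = 0.574, 0.597, 0.574, 0.574 and 0.638 with an estimated correlation. In the exact permutation test of list scores the blood list passed (adjusted p = 0.0176) and the others did not (adjusted p = 0.0705, 0.101, 0.0518 and 0.115 for macrophages, neutrophils, class II genes and endothelium). With slide row as a covariate the macrophage, class II and endothelial calls were lost (adjusted p = 0.0744, 0.303 and 0.385, the highest over 23 alternatives at the preset correlation; shifts -0.29, -0.37 and -0.070), and with slide row 1 alone the class II and endothelial calls (adjusted p = 0.231 and 0.296; shifts -0.38 and -0.080). Both slide row fits rest on the same 2 metformin arrays, so they are not separate checks. The class II list kept its call in 12 of the 23 alternatives (range 0.00635 to 0.303): it was also lost with normexp, median scaling, the mean of a gene's probes and array weights (adjusted p = 0.0554, 0.0566, 0.0653 and 0.0664) and without metformin mouse 6 or CCl4 mouse 3 or 4 (adjusted p = 0.0529, 0.0532 and 0.0604). Hepatocyte markers had 5 lower, 1 higher and 20 uncalled of 26 (5 and 1 adjusted over the list alone), a shift of -0.18 and an adjusted p = 0.0505 with camera. They stayed uncalled in 7 of 23 alternatives at the preset correlation (range 0.00595 to 0.103), with an estimated correlation (adjusted p = 0.574) and with fry (adjusted p = 0.103), and passed the exact permutation test (adjusted p = 0.0176). T and NK cell markers (2 higher and 0 lower of 21, 1 higher adjusted over the list alone) and B and plasma cell markers (1 higher and 2 lower of 14, the same adjusted over the list alone) were not called, at adjusted p = 0.932 for both. Markers of adipose tissue, muscle and pancreas had 2 lower and 0 higher of 8 (2 lower adjusted over the list alone) and were not called (adjusted p = 0.155). Camera did call them without a filter on dim probes (shift -0.27, adjusted p = 0.0233).

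**Figure D2:**
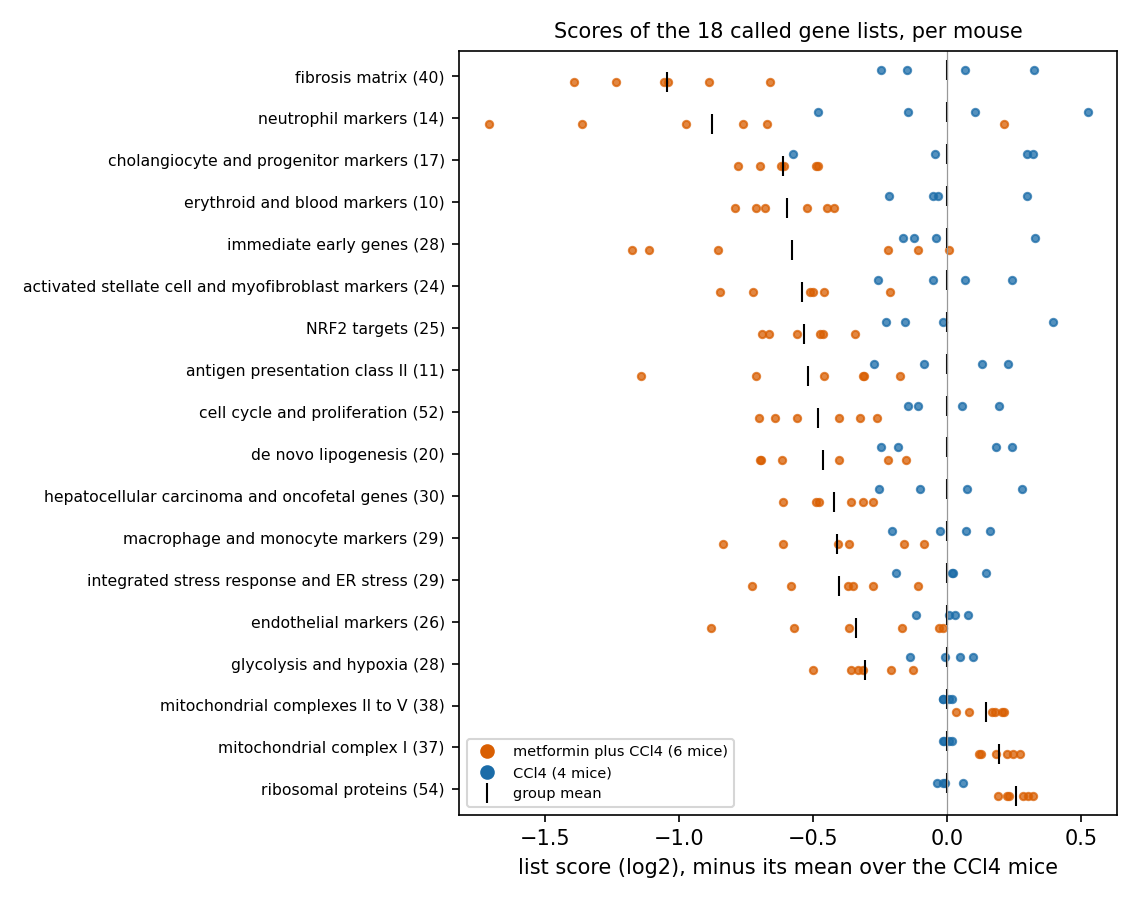
Score of each of the 18 called gene lists per mouse (horizontal axis, log2): the mean of its members minus the mean of all tested features, with the mean over the CCl4 mice set to 0; numbers in brackets are tested members, points are mice and bars are group means. The matrix list differs by -1.05 and the ribosomal list by 0.26, with no overlap of the groups. Scores do not overlap either for the proliferation, NRF2, carcinoma, blood, complex I and complexes II to V lists. In every other called list the scores of the groups overlap. Camera's direction for complexes II to V reversed after scaling to spike-ins.

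Stress and metabolic lists were also lower. Of 25 targets of NRF2, the regulator of the antioxidant response, 12 fell, 1 rose and 12 were not called (12 and 1 adjusted over the list alone), with a shift of -0.55. Gstm2, Gstm4, Hmox1 and Srxn1 were at -0.78, -1.25, -0.94 and -0.76, and cross-hybridisation between the Gstm paralogs was not excluded. Of 29 genes of the integrated stress response and endoplasmic reticulum stress 11 fell, 2 rose and 16 were not called (11 and 2 adjusted over the list alone), with a shift of -0.36. The chaperones and cofactors Calr, Hyou1, Dnajc3 and Sdf2l1 were at -1.27, -2.13, -0.78 and -1.83. Of 28 glycolysis and hypoxia genes 11 fell, 4 rose and 13 were not called (11 and 4 adjusted over the list alone), with a shift of -0.39. The phosphofructokinases Pfkl and Pfkp were at -0.84 and -0.92 and pyruvate kinase Pkm at -1.20, while the hepatocyte glucose transporter Slc2a2 rose by 1.23. Of 28 immediate early genes 10 fell, 3 rose and 15 were not called (10 and 3 adjusted over the list alone), with a shift of -0.86. Jund, Fosb and Btg2 were at -1.43, -0.92 and -1.88 and the heat shock cochaperone Dnajb1 at 1.60. Of 20 lipogenesis genes 8 fell, 3 rose and 9 were not called (8 and 3 adjusted over the list alone), with a shift of -0.46. Srebf1, the transcription factor that drives fatty acid synthesis, Insig2 and Agpat2 were at -1.18, -1.44 and -0.74, and Gpam at -0.73, where a second kept probe gave -0.15. Camera gave adjusted p = 9.01e-04, 0.0111, 0.0108, 0.0159 and 0.0276 for the NRF2, stress, glycolysis, immediate early and lipogenesis lists, each with adjusted p = 0.574 with an estimated correlation, and the exact permutation test adjusted p = 0.0176, 0.0518, 0.0378, 0.132 and 0.0705. Slide row as a covariate ended the immediate early and lipogenesis calls (adjusted p = 0.115 and 0.0918), with shifts of -0.65 and -0.499, the latter no smaller than in the main fit, and slide row 1 alone did so too (adjusted p = 0.0721 and 0.103; shifts -0.66 and -0.51). Both slide row fits rest on the same 2 metformin arrays. The immediate early call was also lost without metformin mouse 6 (adjusted p = 0.0512), and the lipogenesis call without CCl4 mouse 4 (adjusted p = 0.0845) and with array weights (adjusted p = 0.0664), within ranges of 0.00607 to 0.493 and 0.0097 to 0.127 at the preset correlation.

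Gluconeogenesis, which metformin lowers in diabetes, was not called as a list. Of 14 genes 3 rose, 1 fell and 10 were not called (2 and 1 adjusted over the list alone), with a shift of -0.18 and adjusted p = 0.374 with camera. The glucose-6-phosphate transporter Slc37a4 rose by 1.03 ± 0.14 and tyrosine aminotransferase Tat fell by 1.36 ± 0.21 (SE), while Mdh1 and Fbp1 were at 0.29 and 0.24, and at -0.27 and -0.31 after scaling to spike-ins. The Mdh1 call was lost with quantile normalization and median scaling (adjusted p = 0.146 and 0.0843 in limma). The Fbp1 call (adjusted p = 0.0440 in limma) was lost in 8 of the 10 fits that left out 1 mouse, and also in others (range 0.0111 to 0.244). G6pc, the last enzyme of the pathway, differed by -0.61 ± 0.27 without passing (adjusted p = 0.0887 in limma); without metformin mouse 5 or CCl4 mouse 1 it passed (adjusted p = 0.0431 and 0.0357), as it did with quantile normalization (adjusted p = 0.0415) and after scaling to spike-ins (adjusted p = 0.00579), within a range of 0.00579 to 0.213. Cyp2e1, the enzyme that activates CCl4, differed by 0.25 ± 0.12 and did not pass (adjusted p = 0.101 in limma). Targets reported for miR-221 had 6 higher, 3 lower and 13 uncalled of 22 (6 and 2 adjusted over the list alone), with a shift of -0.018 and adjusted p = 0.788 with camera. Cdkn1b, the cell cycle inhibitor p27 and a known miR-221 target, rose by 0.67 ± 0.12 (adjusted p = 0.00123 in limma), but by 0.12 without passing after scaling to spike-ins (adjusted p = 0.654) and without passing with slide row 1 alone (0.61, adjusted p = 0.0571), within a range of 1.88e-04 to 0.654. Hdac6 was at 0.59, and at 0.031 without passing after scaling to spike-ins (adjusted p = 0.894). Tbk1 and Ppp2r2a were at -0.61 and -0.52.

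Of 22 genes of the circadian clock 8 fell, 4 rose and 10 were not called (8 and 4 adjusted over the list alone), and the list was not called (shift -0.48, adjusted p = 0.0895 with camera), except without metformin mouse 5 (adjusted p = 0.0479). Beside Arntl, Npas2 and Per3, the following were named after their values were seen. The repressor Nr1d1 had a log2 fold change of -2.02 ± 0.20, Nfil3 -1.52 ± 0.34 and Bhlhe40 -1.43 ± 0.31, while the transcription factors Dbp, Tef and Hlf rose by 1.67 ± 0.46, 1.71 ± 0.23 and 0.93 ± 0.19 (SE). Clock fell by 0.43 and Per1 by 0.84, and Per2 differed by -0.99 ± 0.53 without passing (adjusted p = 0.151 in limma). The labels give a light-dark cycle but no hour at which livers were taken.

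**Figure D3:**
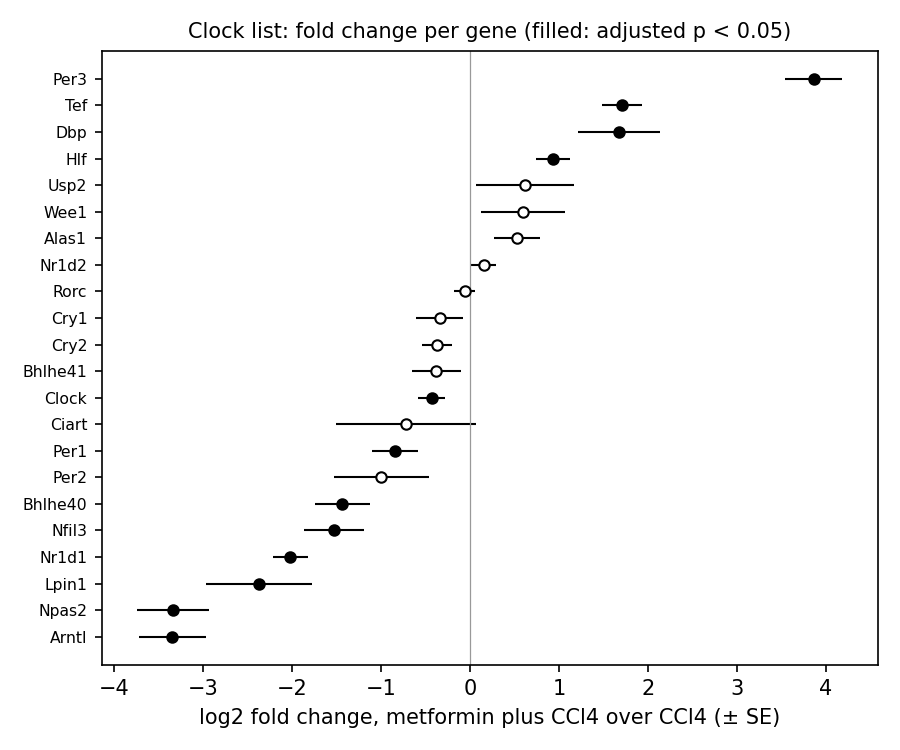
Log2 fold change with metformin (horizontal axis, with its SE as the error bar) of the 22 measured clock genes; filled points passed an adjusted p of 0.05 in limma. Arntl and Npas2 lie at -3.34 and -3.33 and Per3 at 3.86; Npas2 with metformin and Per3 without it were not well above background, so their fitted values are no fold changes and at least 3.74-fold and 4.37-fold hold.

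The authors' deposited table held 4595 probes, 2294 higher and 2301 lower with metformin, of which 3100 have a symbol here (2806 genes). The differences of its group means had the same sign as the 75th-percentile values in 100% of probes, with a Pearson r of 0.999 across probes, which are not independent. Of its probes, 4375 passed the background filter used here, and limma called 100% of those. The authors had selected these probes by FDR and fold change on the same arrays. The shared signs and calls were therefore largely fixed beforehand and check only direction and scale. With quantile normalization, no filter, adjusted p below 0.01 and at least 1.5-fold, limma called 5414 probes, 4558 of them in the authors' deposited table.

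Some other called genes lost their calls in limma with fewer arrays, a covariate or another probe summary. With slide row 1 alone, which leaves 2 metformin arrays, these were Hmox1, Cd14, Hba-a1, Krt19, Cd24a, Ctnnb1, Erg, Csf3r and Mdh1 (adjusted p = 0.0627, 0.0520, 0.0823, 0.0835, 0.0858, 0.0839, 0.0677, 0.0555 and 0.156), with log2 fold changes of -0.84, -0.99, -0.71, -1.12, -0.97, 0.44, 1.16, 0.52 and 0.25. With slide row as a covariate they were Hba-a1, Krt19, H2-DMa, H2-Aa, Cd80 and Mdh1 (adjusted p = 0.0818, 0.0564, 0.0735, 0.0839, 0.0670 and 0.0899), with log2 fold changes of -0.71, -1.12, -0.56, -0.74, 0.50 and 0.25. The group difference of that fit rests on the same 2 metformin arrays as the fit of slide row 1 alone. Gpam lost its call with the mean of its probes (adjusted p = 0.0581). With normexp some genes stayed called with changes smaller by over 1.5 times: Loxl1 -1.36, Ccna2 -0.87, Des -0.65, Itga2b -0.48, Krt7 -0.41, Erg 0.35, Retnlg -1.22 and Ngp -1.06. Some list shifts moved by over 1.5 times while the call held. With normexp they were -0.63 for the matrix, -0.33 for proliferation, -0.40 for bile duct, -0.51 for blood, -0.59 for neutrophils, -0.27 for macrophages, -0.38 for immediate early genes, -0.24 for glycolysis, -0.23 for the stress response, 0.28 for complex I and 0.23 for complexes II to V. Without a filter on dim probes they were -0.32 for blood, -0.39 for immediate early genes, -0.45 for bile duct, -0.69 for class II genes and 0.19 for complexes II to V. The ribosomal shift was 0.12 with quantile normalization, the lipogenesis shift -0.27 with probes above background on all 10 arrays, the neutrophil shift -1.54 and the macrophage shift -0.26 with slide row 1 alone, the class II shift -0.68 without metformin mouse 2 and the endothelial shift -0.16 without metformin mouse 6.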

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

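All tests of the 3 patterns weighed below and of the spike-ins were chosen after the results were seen; the counts over other splits of the arrays were planned before. Of 226 groups of values tested for a single mouse far from the rest, 6 stood out. Genes named for a small p or for groups that do not overlap are less likely to hold such a mouse. The 1 in 20 that chance gives is therefore no reference for this count. Among metformin mice these were mouse 5 for Clec2d (2.75 on the log2 scale, the others 3.29 to 3.58) and mouse 3 for Des (-2.45, the others -3.22 to -2.94). Among CCl4 mice they were mouse 2 for Ccnjl (-2.54, the others -2.95 to -2.91), mouse 3 for Itga8 (2.15, the others 1.14 to 1.23), mouse 2 for Erg (-5.21, the others -4.03 to -3.93) and mouse 2 for Plvap (4.15, the others 3.70 to 3.74). The E1A spike-in transcripts, added in fixed amounts and not part of the gene comparison, lay 0.56 higher with metformin on the log2 scale relative to the 75th percentile (8 transcripts well above background on all arrays, range 0.34 to 0.77, exact permutation p = 0.00952, two-sided). On slide row 1 alone, which held all CCl4 arrays, the difference was 0.33 (mean levels 3.83 for 2 metformin and 3.497 for 4 CCl4 arrays, exact permutation p = 0.133), and the 4 metformin arrays on slide row 2 were at 4.17, so its size, and that of the scaling built on it, differs with slide row.

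Chance assignment of mice was excluded for the gene counts: of 100 splits of the arrays, only the real 1 gave as many genes higher (4024, highest other 256) or lower (2859, highest other 297). It was not excluded for the number of gene lists called at the preset correlation, since 19 of 100 splits called at least as many (18, highest other 22), and the median over the other splits was 11 lists, although 96 of these splits called no gene. The number of lists called by camera therefore does not set metformin apart from other groupings of the mice. Of the lists, 11 of the 18 also passed the exact permutation test of list scores.

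The first pattern is the breadth of the change, with 47.4% of named genes called. A distortion of the signal scale that depends on brightness is argued against by quantile normalization, which left 91.6% of the calls with the same sign. Calls were not confined to genes near background: at a split by the median of their mean signal, 50.8% of the brighter genes were called, against 43.9% of the dimmer ones. All these genes had passed the background filter, and noise within groups lowers the share called. The split therefore cannot tell how far noise affected the dimmer genes. That split took the place of a stricter filter whose result had been seen. Slide, scan day and handling cannot be told apart from metformin, since each group had its own slide; the group differences of the 8 spike-ins had an SD of 0.144, against 0.665 for genes, but spike-ins do not pass through tissue handling and RNA extraction. Animal numbers at the start of the sample titles also fall in separate ranges for the groups. A difference in cohort therefore cannot be told apart from metformin either. A response to metformin stays open, untested against these.

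The second pattern is the clock genes, and neither explanation tested was excluded. Livers taken at different times of day may account for it, but the test left this open: without Arntl, Npas2, Per3 and Dbp, in which the pattern was noticed, 3 genes grouped with Arntl differed from 10 grouped with Dbp and Per3 by -0.67 (means -0.77 and -0.093, exact permutation p = 0.329 over genes, which are not independent). With those 4 genes the difference was -2.18 (exact permutation p = 0.0166), which restates the pattern and uses fitted values below background. Of the genes grouped with Dbp, 5 were negative like Arntl, Nr1d1 and Per1 among them. The members of this group need not peak at the same hour, so a difference in collection time need not move them alike. Their mixed signs therefore do not speak against such a difference, and the contrast cannot decide. A different mix of cell types also stays open, and the test could not have excluded it. Exclusion required the lower limit of the change of all 12 called clock genes to exceed the largest shift of any of 10 cell type lists. That shift was 1.02 in size (neutrophils), and 6 of the 12 genes exceeded it. Clock, Per1 and Hlf had fitted changes of only -0.43, -0.84 and 0.93. The median of a list also sets no limit on the change that a cell mix can give a single gene. An action of metformin on the clock was not tested.

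The third pattern is the fall of matrix genes. A larger share of hepatocytes thinning every other cell type is argued against by the medians, which did not fall alike: the matrix median (-0.88) lay below that of the endothelial list by more than the spread of members (difference -0.67, 95% bootstrap interval over members -0.93 to -0.35) and below 6 of 9 such lists in all, while the neutrophil, erythroid and bile duct lists (-0.92, -0.68 and -0.60) lay near it and the T and NK and B and plasma cell lists at 0.016 and 0.091. Members are not independent (estimated correlation 0.31 in the matrix and 0.46 in the endothelial list). The intervals in this paragraph treat members as independent and leave out the spread between mice, so they are likely too narrow. Fewer stellate cells and myofibroblasts could not be decided: the matrix median lay below that of the marker list (difference -0.56, interval -0.999 to -0.0064), just outside 0, which a first form of the test read against it. A condition added after that result keeps it open, as 7 of the 24 markers fell at least as far as the matrix median and some are not restricted to these cells. Less matrix expression per cell, and a difference between slides, stay open.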

How the results depend on the processing

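Spike-in scaling and the exact test of list scores were added after seeing the data. Counts of genes higher, genes lower and lists stayed within 1.5 times the main counts (4024, 2859 and 18) under normexp, quantile and median normalization, both filters, both other probe summaries, irregular spots kept and both variance models, where each was run. With a minimum of 1.5-fold, 2095 genes were higher and 1820 lower, because fewer genes can pass. Slide row as a covariate, where the group difference rests on the 2 metformin arrays of row 1, gave 2892, 2056 and 12. With slide row 1 alone, 2369 were higher and 1847 lower, with 2 metformin mice left. Spike-in scaling gave 541 higher, 6650 lower and 4 lists (fibrosis matrix, cell cycle, NRF2 and hepatocyte markers); the spike-in difference between groups alone gave 859, 8622 and 4, and the deviations within groups alone 2263, 1822 and 17. Among genes called in both fits 0 changed sign. Under spike-in scaling these genes called in the main fit changed sign: Rpl26 (-0.047), Ndufa6 (-0.016), Ctnnb1 (-0.058), Uqcrfs1 (-0.013), Cox7c (-0.022), Sdhd (-0.14), Csf3r (-0.11), Mdh1 (-0.27) and Fbp1 (-0.31). Cyp2e1, called in neither fit, went from 0.25 to -0.30. Among the 18 called lists only camera's direction for complexes II to V changed, and the shift of that list stayed at 0.13. With an estimated correlation 0 lists were called by limma's camera (0 at an unadjusted p below 0.05, lowest 0.0582); fry called 16, 13 of them among the 18; the exact test of list scores called 14, 11 of them among the 18. Leaving out 1 array gave 3515 to 3924 genes higher, 2376 to 2742 lower and 16 to 20 lists. The Pearson r with the authors' deposited table, 0.9992 across probes, was 0.9995 with quantile normalization and 0.884 with normexp, where 99.9% of signs were shared; the cause was not tested. Mouse numbers 1 to 4 occur in both groups but belong to different mice, and deviations from the group means correlated at -0.14, -0.12, 0.085 and -0.0034 for them, so they share only a number (0 of 4 CCl4 mice were closest to the metformin mouse of their number); with the replicate block 2609 genes were higher, 2067 lower and 18 lists called, 15 of them among the main 18 (not class II, lipogenesis and endothelium, adjusted p = 0.0860, 0.107 and 0.166). It called Col1a1 (adjusted p = 0.0185) and not Cd68, Lgals3, S100a8, Acta2, Mdh1 and Fbp1 (0.0513, 0.0548, 0.0698, 0.0979, 0.128 and 0.134). Of the 106 called genes named, 76 stayed called with the same sign in every alternative that tested them except spike-in scaling, the 1.5-fold minimum included. Some of the 76, Per3 and Npas2 among them, were tested in only 24 of the 25 alternatives. Over all alternatives, named genes stayed on their side of the threshold, with the same sign where called, in 2646 fits. They lost a call in 67, gained one in 11 and changed sign with a call in either fit in 9. Sign changes of genes called in neither fit, such as that of Cyp2e1, count among the 2646. For lists, over the alternatives at the preset correlation only and by the same rule, these counts were 782, 42, 26 and 1. Signal over background limits the 56 higher and 66 lower genes that were not well above background on any array of one group.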

Other observations

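The gene groups here belong to lists fixed before the data were examined that camera did not call, and their genes were named after the values were seen. The exact permutation test was also chosen after the data were seen. Values are log2 fold changes, metformin plus CCl4 over CCl4. Genes of WNT signalling and of hepatocytes around the central vein, where CCl4 does most damage, had 10 higher, 4 lower and 8 uncalled of 22 (10 and 4 adjusted over the list alone), with a shift of 0.29 and adjusted p = 0.374 with camera and 0.0176 in the exact permutation test of list scores. Fry, which tests against no change and not against other genes, gave adjusted p = 0.0164. Rnf43, Tbx3, Sp5, Lgr5 and Glul, glutamine synthetase, were at 2.33, 2.17, 1.402, 1.28 and 1.05, and Cyp1a2 and Cyp27a1 at -1.21 and -1.01. In bile acid synthesis and transport (6 higher and 5 lower of 22, the same adjusted over the list alone, adjusted p = 0.516) Cyp7a1 and the bile acid receptor Nr1h4 were at 2.79 and 1.53, and the repressor Nr0b2 and Cyp8b1 at -1.36 and -1.05. Of 20 components of AMPK and mTORC1 signalling, a pathway tied to metformin, 9 were higher and 4 lower (10 and 5 adjusted over the list alone; adjusted p = 0.856 with camera against other genes, and 0.00732 with fry against no change). The kinase subunit Prkaa1 was at 0.60 and Tsc2 at 1.08 (well above background on 1 of 4 CCl4 arrays), and Stk11, which activates AMPK, at -0.74. Of 24 p53 targets and apoptosis genes 5 were higher and 9 lower (6 and 9 adjusted over the list alone, shift -0.40, adjusted p = 0.121, and 0.0176 in the exact permutation test): Cdkn1a, Trp53inp1 and Phlda3 were at -4.50, -2.08 and -1.20, whereas Zmat3, Bax and Mdm2 were at 1.07, 0.80 and 0.34.

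Fatty acid oxidation (8 higher and 4 lower of 29, 8 and 3 adjusted over the list alone, adjusted p = 0.203) held Ppara, its main transcription factor, at 1.96 and Cyp4a14 at 3.92. Cholesterol synthesis (3 higher and 6 lower of 24, the same adjusted over the list alone, adjusted p = 0.0895) held Insig1 at -1.04. Xenobiotic metabolism had 7 higher and 7 lower of 30 (the same adjusted over the list alone, adjusted p = 0.451), with Ugt2b1 at -1.41. Inflammatory cytokines and NF-kB targets had 2 higher and 5 lower of 25 (the same adjusted over the list alone, adjusted p = 0.0893), with Nfkb1 at -1.12 and Cxcl1 at 2.24. Interferon response genes had 6 higher and 5 lower of 29 (the same adjusted over the list alone, adjusted p = 0.267), with Rsad2 at -1.59 and Oas2 at 1.02. Of 23 alternatives at the preset correlation, cholesterol synthesis stayed uncalled in 19 and fatty acid oxidation and the inflammatory list in 21 each. Growth hormone and sex-biased genes had 4 higher and 7 lower of 32 (4 and 5 adjusted over the list alone, adjusted p = 0.213). Periportal genes had 3 higher and 3 lower of 22 (0 and 2 adjusted over the list alone, adjusted p = 0.203), with Cps1 at -0.75. Acute phase genes had 1 higher and 3 lower of 27 (0 and 3 adjusted over the list alone, adjusted p = 0.731), with Fga at -1.25. The signs of the median, the mean and the test differed for acute phase genes (median shift 0.078, mean shift -0.077), for AMPK and mTORC1 (0.067 and -0.081) and for T and NK cells (-0.085 and 0.037).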
